A study of Mus musculus with 27 samples.

How the data were processed

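RNA was sequenced from dural macrophages of Rag1-deficient B6 mice, which make no T or B cells of their own. Per the labels, the mice were 16 to 19 weeks old and were either left without T cells or studied 6.5 weeks after reconstitution with T cells. The donor T cells were total B6 T cells, or T cells that lacked T-bet, interferon-gamma, the interleukin-6 and interleukin-21 receptors, interleukin-17A and F, or interleukin-22. Per the labels' protocols, blood was flushed out with saline, the dura mater was removed and digested, macrophages were sorted on a flow cytometer, and libraries were made from total RNA with an unstranded kit and read from a single end. The sort's markers are not given in the sources used here. Genes on opposite strands that overlap cannot be told apart in such libraries.

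The deposited table holds whole-number read counts per gene for 27 libraries. Its name calls the values normalized, but in each of the 27 columns every count from 1 to 20 occurs and the totals differ between columns, so the values were treated as raw counts. Per the submitters' processing notes, STAR 2.4.0j, featureCounts, DESeq2 1.20.0 and the GRCm38 genome were used. How featureCounts treated reads that match several places is not given in the sources used here. The table has 41388 gene identifiers, of which 40254 have a symbol in the GENCODE M21 annotation of GRCm38. Identifiers without a symbol took from 0.106% to 0.143% of a library's counts. Coordinates are GRCm38 positions from GENCODE M21. Library totals ran from 6902602 to 19966749 counts.

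The columns were matched to samples by name. They show the group and the sex but carry no replicate number of the sample titles, so libraries are named here by group, sex and a running number (F1, M1). The labels do not say that libraries of a group came from separate animals, so p-values measure the spread between these libraries, technical spread included. The libraries of a group were compared in pairs by a chi-square test of their counts over genes with at least 20 counts in the pair. The chi-square per degree of freedom lay between 8.97 and 138 over 52 pairs, so each pair differed by more than sampling noise. This does not show that the libraries of a pair come from separate animals. The column names leave open that the 2 T-bet libraries, with 11.7 for their pair, come from 1 animal, and that some other libraries are pools. Every library was counted once, and if the T-bet pair is 1 animal, that group has an n of 1.

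The groups, the tests, the gene lists, the rule for named genes and a first series of alternatives were fixed before the data were examined. The planned test was limma on log2 values, with edgeR's quasi-likelihood test to replace it if the file held raw counts, which it did. Genes with a mean normalized count of at least 10 over the 27 libraries were kept, which left 12682. One edgeR model (version 4.0.16, R 4.3.3, TMM scaling) was fitted to all 27 libraries with the group and the sex as additive terms. Each comparison is a contrast of that model, except sex by group. Sex by group was tested in a model of its own, on the no T-cell and IL-6Ra/IL-21R groups alone. P-values were adjusted by the Benjamini-Hochberg method within a comparison, and a gene was called at an adjusted p (q) under 0.05. A log2 fold change is given ± its standard error, and levels are means of CPM, which are counts scaled to the library total times its TMM factor, ± SD over the libraries of a group. The CPM of ribosomal protein genes by library and set use the plain total. The fold against a group in which all libraries had a count of 0 was computed against 3 counts over the group. The tested comparisons were total T cells against no T cells, each knockout group against total T cells and against no T cells, the mean of the 6 T-cell groups against no T cells, males against females, any difference among the 7 groups, and sex by group.

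Of 27 gene lists, 25 had enough measured members for a list test. They cover the interferon-gamma response, MHC class II, MHC class I antigen processing, the type I interferon response, interleukin-17 and NF-kB target genes, alternative activation, genes typical of border macrophages, genes typical of monocyte-derived cells, complement, Fc receptors, chemokines, costimulation and checkpoint genes, cytokine receptors, cholesterol synthesis, the cell cycle, and early-response genes that tissue digestion induces. The others hold markers of T cells, B cells, neutrophils, NK cells, dendritic cells, microglia, fibroblasts, endothelial cells, mast cells, erythroid cells and osteoclasts. A list is described by the median log2 fold change of its measured members and by the number of members called, over all genes tested and adjusted over the list alone. The lists were tested with camera (limma 3.58.1) at a preset correlation between genes of 0.01, and with an estimated correlation and fry as alternatives. A list's score in a library is the mean log2 CPM of its members, with a prior count of 2. Two-sided exact permutation tests of these scores, adjusted over the 25 lists of a comparison, were added after the data were seen. So were splits of the libraries into random groups of the same sizes, up to 100 per comparison with seed 7. Genes targeted in the donor T cells and sex-linked genes were looked up as checks.

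The genes named follow the fixed rule: the 10 largest increases and the 10 largest decreases among called genes with a mean of at least 50 normalized counts and a regular symbol, up to 4 called members of each list by smallest p or else the member with the smallest p, and the most abundant member of each list of other cell types. The text names part of what this rule gave. Some of the genes it gave are not reported here.

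The libraries fell into 3 sets by the summed CPM of 78 ribosomal protein genes, with limits of 20000 and 10000 chosen after seeing the data. Set A has 7 libraries, set B 13 and set C 7. Fits with the set as a term, and fits in set A or set B alone, were added for this reason. Genes that share sequence with another gene were found by aligning GENCODE transcripts to each other with minimap2 2.31. A gene was called a copy gene when at least 50% of its length aligned at 90% identity or more to a transcript of another gene. Such genes are marked where they are named.

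The test script was tested on simulated data with 100 genes changed by 1 and 100 changed by 2 on the log2 scale. Counts were drawn for each gene on its own around its overall mean, without library sets. The rates below therefore need not hold for the real libraries. For total T cells against no T cells it recovered 62 of the 100 smaller and 91 of the 100 larger changes, with 9 false calls among 162 (5.56%). For T cells without the interleukin-6 and interleukin-21 receptors against total T cells it recovered 60 and 95, with 14 false calls among 169 (8.28%, above the 5% of the threshold). For T cells without interleukin-22 against total T cells it recovered 43 and 87, with 3 false calls among 133. For T cells without T-bet against total T cells it recovered 29 and 85, with 6 false calls among 120. The alternatives tried were no filter on low counts, no sex term, female libraries alone, only the compared groups in the fit, leaving out each library in turn, and limma with a pseudocount of 5, which were planned, and DESeq2 1.42.0, median-ratio size factors, limma with a pseudocount of 1 and the fits by set, which were added later.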

Results

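RNA of sorted dural macrophages was sequenced from Rag1-deficient mice with and without transferred T cells, in 27 libraries of 7 groups. There were 6 libraries from mice without T cells (4 female, 2 male) and 5 from mice given total B6 T cells (4 female, 1 male). T cells that lacked T-bet, interferon-gamma (IFN-gamma) or interleukin-17A and F (IL-17A/F) gave 2 female libraries each. T cells without the interleukin-6 and interleukin-21 receptors (IL-6Ra/IL-21R) gave 7 (3 female, 4 male), and T cells without interleukin-22 (IL-22) gave 3 (2 female, 1 male). The libraries held from 6902602 to 19966749 counts, and from 13225 to 17015 genes were detected in each.

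The knockouts were made in the donor T cells and the sequenced cells were macrophages, so the counts cannot show whether a knockout worked. Ifng had up to 61 counts in the total T-cell group, with 0 in 3 of its 5 libraries. It had 0 counts in all libraries of the T-bet, IFN-gamma, IL-6Ra/IL-21R and IL-17A/F groups. Tbx21, which encodes T-bet, had 0 counts in the T-bet, IFN-gamma and IL-17A/F groups and up to 41 with total T cells. Il17a was counted in 1 library, a total T-cell library with 16 counts, and Il22 had 0 everywhere. Il17f had 5 counts in 1 IL-6Ra/IL-21R library. Il6ra (1134 to 2956 counts) and Il21r (602 to 3094) were present in every library, with or without T cells. Rag1 had 0 to 41 counts. The sex labels matched in all 27 libraries. Xist had 744 to 3436 counts in the 19 female and 0 to 194 in the 8 male libraries, and Ddx3y had 0 to 92 and 1046 to 1749.

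The libraries fell into 3 sets by their ribosomal protein transcripts, and the sets cross the groups only in part. Set A holds 4 libraries without T cells and 3 with total T cells. Set B holds 2 of each of these groups, 6 of the IL-6Ra/IL-21R group and the 3 of the IL-22 group. Set C holds the T-bet, IFN-gamma and IL-17A/F groups and 1 IL-6Ra/IL-21R library. The 3 groups in set C share no set with a control, so their differences from a control cannot be told from differences between sets.

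RNA of the sorted dural macrophages differed widely between mice with total T cells and mice without T cells. Whether the cells themselves or the mix of sorted cells changed stays open. Genes of the IFN-gamma response and of antigen presentation rose, genes typical of monocyte-derived cells rose, and genes typical of resident border macrophages fell. Of 24 IFN-gamma response genes 19 were called higher, with a median log2 fold change of 1.49, and 15 of 17 border macrophage genes were called lower, with a median of -1.41. Both list medians had the same sign in sets A and B. In all, 2663 of 12682 genes were called, 1476 higher and 1187 lower (4268 at an unadjusted p under 0.05). Females alone gave 1564, set A alone 2111 and set B alone, with 2 libraries against 2, gave 92. Of these 92 genes, 74 were also called in set A, all in the same direction. No gene was called for a difference of the effect between sets (edgeR, 1276 unadjusted). With 2 libraries against 2 in set B this does not show that the effects are alike.

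Genes of the IFN-gamma response rose together. The 19 called members of this list became 22 when adjusted over the list alone, and none was lower. The median was 1.73 in set A and 1.01 in set B. The list score was 6.77 ± 0.882 with and 4.85 ± 0.351 without T cells (adjusted exact permutation p = 0.00676 over 462 splits, and 0.0132 with splits within sets). Camera gave an adjusted p of 1.72e-20, against an adjusted p = 0.0915 with an estimated correlation. Gbp2 (chromosome 3, 142620602 to 142638008, + strand), a GTPase that attacks pathogens inside cells, rose by 3.09 ± 0.38 (q = 1.96e-05, set B 2.15), from 96.5 ± 43.2 to 825 ± 608 CPM. Its relative Gbp4 rose by 3.23 ± 0.41 (q = 2.87e-05, set B 2.48). Cxcl9, a chemokine that draws T cells (chromosome 5, 92321347 to 92328079, - strand), rose by 4.41 ± 0.69 (q = 0.000111, set B 3.86), from 47.6 ± 47.3 to 1001 ± 793 CPM. The checkpoint ligand Cd274 rose by 2.95 ± 0.39 (q = 3.09e-05, set B 1.80 with q = 0.0621). Nos2, the inducible nitric oxide synthase (chromosome 11, 78920787 to 78960254, + strand), rose most of the named genes, by 5.93 ± 1.38 (q = 0.00356, set B 8.16 with q = 0.183). Its level was 91.7 ± 133 CPM with T cells, so it differed much between libraries. Acod1, which makes itaconate (chromosome 14, 103046977 to 103056573, + strand), rose by 5.12 ± 0.74 (q = 5.89e-05, set B 4.51).

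Antigen presentation genes rose for both MHC classes. Of the MHC class I and antigen-processing list 18 of 19 members were called higher, and 18 when adjusted over the list alone (median 1.12, set A 1.30, set B 0.71). Its score rose by 0.999 (adjusted exact p = 0.00676). Camera gave 1.08e-21, against an adjusted p = 0.0678 with an estimated correlation. The peptide transporter Tap1 (chromosome 17, 34187553 to 34197225, + strand) rose by 1.72 ± 0.20 (q = 1.53e-05, set B 1.18), from 218 ± 29.5 to 719 ± 252 CPM. The immunoproteasome subunit Psmb8 rose by 1.34 ± 0.18 (q = 3.09e-05, set B 0.85). Of the MHC class II list 6 of 11 members were called higher, and 10 when adjusted over the list alone (median 0.73, set A 0.67, set B 0.83). Its score rose by 0.953 (adjusted exact p = 0.00676). Camera gave 0.000142, against an adjusted p = 0.383 with an estimated correlation. H2-DMa, which helps to load peptides on class II (chromosome 17, 34119541 to 34139101, + strand), rose by 0.73 ± 0.18 (q = 0.00634, set B 0.83), from 660 ± 49.9 to 1109 ± 44.6 CPM.

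Fc receptor genes rose in 4 of 5 members, and 4 when adjusted over the list alone (median 0.39). The score rose by 0.626 (adjusted exact p = 0.00676), and camera gave 0.000233, against an adjusted p = 0.0563 with an estimated correlation. Fcgr4, an activating receptor for IgG (chromosome 1, 171018920 to 171029761, + strand), rose by 1.82 ± 0.18 (q = 5.32e-06, set B 1.45), from 134 ± 19.0 to 476 ± 111 CPM.

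The list of monocyte-derived cells rose in 13 of 14 members, also when adjusted over the list alone (median 2.46, set A 2.76, set B 1.51). Its score was 7.91 against 5.68 (adjusted exact p = 0.00676). Camera gave 3.55e-10, against an adjusted p = 0.1001 with an estimated correlation. The integrin Itgal rose by 2.35 ± 0.31 (q = 3.23e-05) and the coagulation factor F10 by 4.53 ± 0.84 (q = 0.000528). The border macrophage list fell in 15 members, also when adjusted over the list alone (set A median -2.01, set B -0.83). Its score was 7.77 against 9.23 (adjusted exact p = 0.00676). Camera gave 4.49e-14, against an adjusted p = 0.0932 with an estimated correlation. Cbr2, a carbonyl reductase (chromosome 11, 120729489 to 120732114, - strand), changed by -1.83 ± 0.29 (q = 0.000122, set B -1.15), from 994 ± 155 to 289 ± 187 CPM. Gas6, a ligand for the uptake of dead cells, changed by -1.52 ± 0.27 (q = 0.000321). The chemokine Pf4 changed by -1.55 ± 0.30 (q = 0.000875) and the growth factor Igf1 by -1.44 ± 0.28 (q = 0.000791). The mannose receptor Mrc1 changed by -0.99 ± 0.27 (q = 0.0108) and Csf1r, the receptor for macrophage colony-stimulating factor, by -0.44 ± 0.10 (q = 0.00367). Genes of the microglia list fell in 7 of 9 members, and 8 when adjusted over the list alone (median -1.15). Its score changed by -1.25 (adjusted exact p = 0.00676), and camera gave 2.37e-07, against an adjusted p = 0.0563 with an estimated correlation. Fcrls of this list changed by -1.93 ± 0.34 (q = 0.000299).

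The largest decreases included Slc40a1, which exports iron (chromosome 1, 45908068 to 45926523, - strand). It changed by -2.96 ± 0.54 (q = 0.000446, set B -2.35 with q = 0.122), from 173 ± 41.2 to 23.1 ± 18.1 CPM. The lectin Siglech (chromosome 7, 55768178 to 55778925, + strand) changed by -2.70 ± 0.37 (q = 3.86e-05, set B -2.27 with q = 0.0854). Ccl24, which draws eosinophils, changed by -2.54 ± 0.52 (q = 0.00118). The largest increases included the acute-phase gene Saa3 (5.32 ± 1.62, q = 0.0209), Arg1, which breaks down arginine (5.08, q = 0.0185), and Upp1, which splits uridine (5.36 ± 1.11, q = 0.00139). Kynu of the kynurenine pathway rose by 4.55 ± 0.77 (q = 0.000228).

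Single inflammatory genes rose, while camera called none of the lists that hold them and the scores of 3 of these 5 lists passed the exact test. The prostaglandin synthase Ptgs2 rose by 2.69 ± 0.31 (q = 1.53e-05, set B 1.63), from 228 ± 99.2 to 1467 ± 595 CPM. Il1b rose by 1.80 ± 0.33 (q = 0.000457) and complement C3 by 3.43 ± 0.52 (q = 8.61e-05). The chemokine Ccl5 rose by 4.09 ± 0.76 (q = 0.00056), the cytokine receptor chain Csf2rb by 1.66 ± 0.25 (q = 7.45e-05) and Cd40, through which T cells activate macrophages, by 1.89 ± 0.25 (q = 3.09e-05). The IL-17 and NF-kB target list had 3 of 17 members higher and 2 lower (median 0.23, camera adjusted p = 0.0792, adjusted exact p = 0.165). The chemokine list had 6 of 20 higher and 2 lower (median -0.02, mean 0.45, camera 0.461, exact 0.0732). Costimulation and checkpoint genes had 4 of 11 higher (median 0.17). Camera did not call them (0.127), but their score rose by 0.741 (adjusted exact p = 0.00676). Alternative activation (median 0.27, mean 0.92), complement (median -0.14, mean 0.39) and cytokine receptors (median 0.09) were not called by camera (0.984, 0.972 and 0.234), which put the first pair as lower. Their scores rose by 0.741, 0.312 and 0.173 (adjusted exact p = 0.0225, 0.0464 and 0.025). Cholesterol synthesis was called higher by camera (0.00949, against an adjusted p = 0.432 with an estimated correlation) but not by its score (adjusted exact p = 0.0613). Of its 16 members 5 were higher, and 6 when adjusted over the list alone (median 0.38).

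The type I interferon list was not called. It had 1 of 21 members higher and 2 lower (median 0.05, camera direction lower with 0.971, adjusted exact p = 0.894). Oas2, an antiviral sensor of double-stranded RNA, changed by -1.30 ± 0.17 (q = 3.09e-05, set B -1.18). Isg15, a copy gene, rose by 0.69 ± 0.24 (q = 0.0378, set B -0.12 with q = 0.827). The cell-cycle list was called lower by camera (median -0.36, 4 of 25 members, 3 when adjusted over the list alone, 0.024), against an adjusted p = 0.582 with an estimated correlation and an adjusted exact p = 0.174. Cenpf changed by -1.76 ± 0.53 (q = 0.0195) and Mcm6 by -0.80 ± 0.17 (q = 0.00167). Early-response genes that tissue digestion induces were lower in 6 of 18 members, and 7 when adjusted over the list alone (median -0.43). Camera gave 0.000607, against an adjusted p = 0.256 with an estimated correlation, and their score changed by -0.510 (adjusted exact p = 0.0148).

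Markers of other cell types also moved with this comparison. The fibroblast list was lower in 3 of 10 members, and 4 when adjusted over the list alone (median -1.17). Camera gave 0.00128, against an adjusted p = 0.424 with an estimated correlation, and the score changed by -1.18 (adjusted exact p = 0.0108). The collagen gene Col1a1 (chromosome 11, 94936224 to 94953042, + strand) changed by -1.56 ± 0.45 (q = 0.0147, set B -2.08). The dendritic cell list had 3 of 10 members higher and was not called by camera (median 0.71, 0.104), but its score rose by 1.22 (adjusted exact p = 0.0108). The B-cell (median -0.45), neutrophil (-0.68, camera direction higher), endothelial (0.12), mast-cell (0.12), erythroid (-2.89) and osteoclast (-0.08) lists were not called. Their camera adjusted p was 0.190, 0.621, 0.895, 0.420, 0.482 and 0.443. Of the T-cell and NK-cell lists only 2 genes each could be tested. By the exact tests 14 of the 25 lists passed, and 13 with splits within sets.

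**Figure D1:**
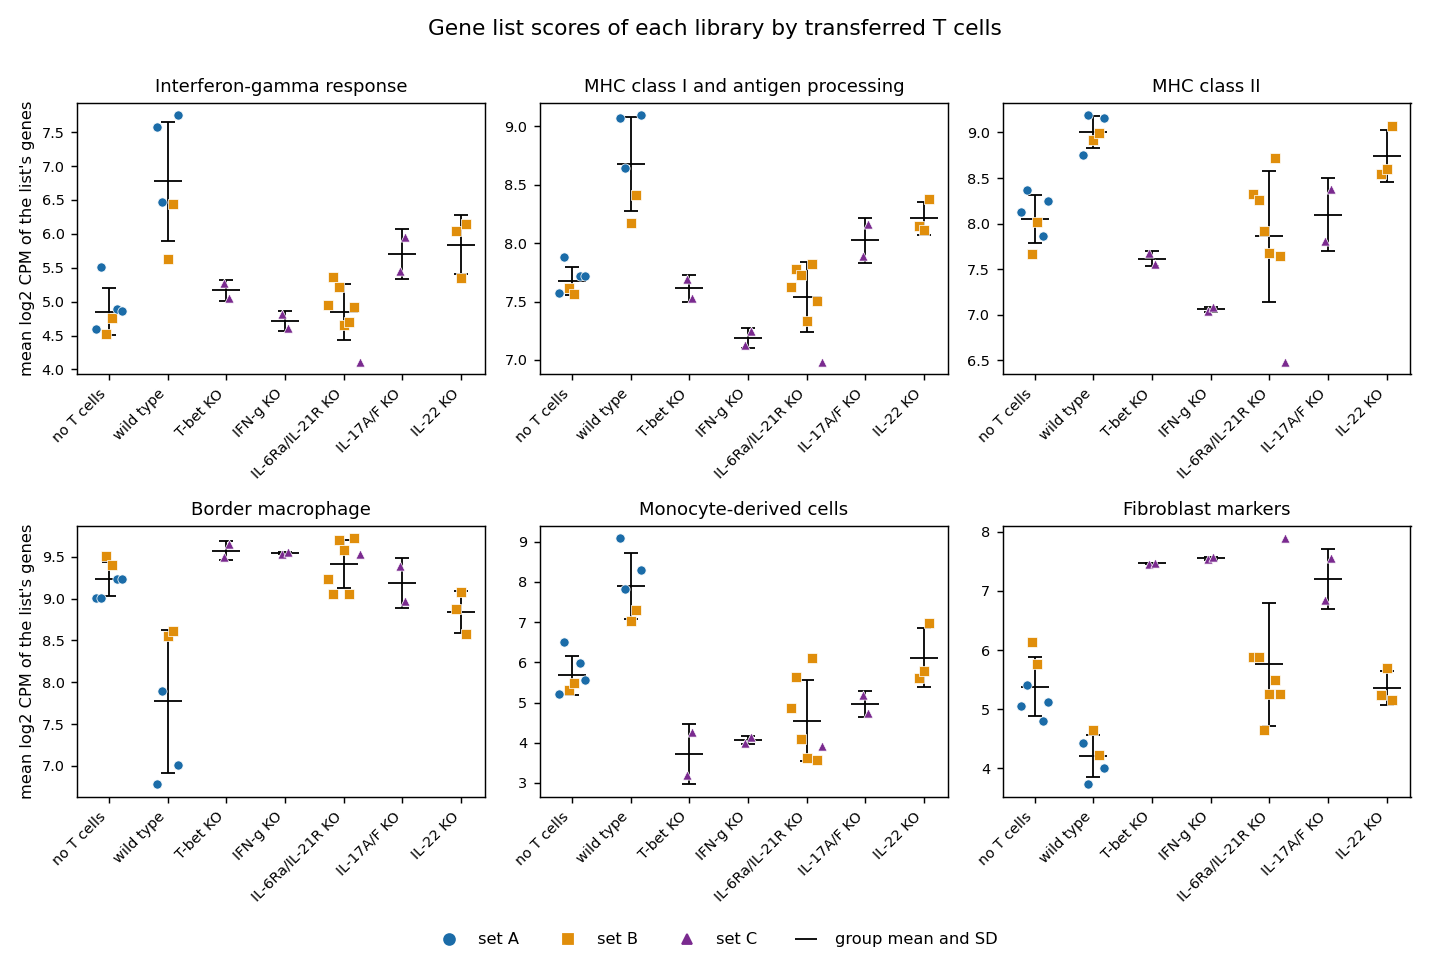
Scores (mean log2 CPM) of 6 gene lists in each library by group, with marker and colour by library set. Black lines give the mean ± SD of a group, such as 6.77 ± 0.882 for the IFN-gamma response with total T cells and 4.85 ± 0.351 without T cells.

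**Figure D2:**
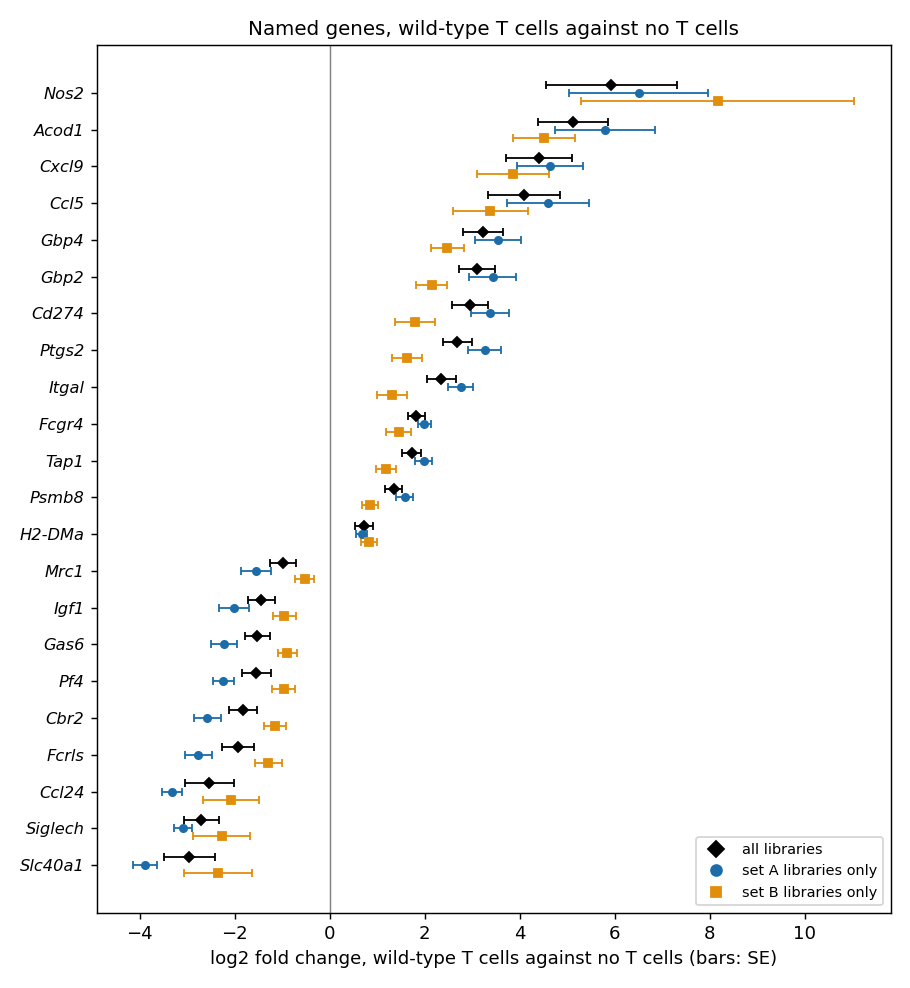
Log2 fold changes ± SE of named genes for total T cells against no T cells, in all libraries and in sets A and B alone. Gbp2, for example, rose by 3.09 in all libraries and by 2.15 in set B.

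Macrophages of mice given T cells without IL-6Ra and IL-21R differed widely from those with total T cells. IFN-gamma response genes were lower in 22 of 24 members (median -1.54), MHC and monocyte-derived genes were lower, and border macrophage genes were higher in 16 of 17 members (median 1.69). The medians had the same signs within set B. In all, 3565 genes were called, 1657 higher and 1908 lower (4915 unadjusted). Set B alone gave 827 (303 higher, 524 lower), females alone 1990, and a fit with the library set as a term 1810.

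The IFN-gamma list had 22 members lower when adjusted over the list alone as well. Its score was 4.85 ± 0.412 against 6.77 ± 0.882 (adjusted exact p = 0.00316 over 792 splits), and its set B median was -0.75 with 12 lower and 1 higher. Camera gave 1.65e-17, against an adjusted p = 0.104 with an estimated correlation. Within set B no list score passed (28 splits, lowest adjusted exact p = 0.0558), where a smallest possible exact p of 0.0357 leaves little room to pass. Gbp2 was lower by -3.15 ± 0.36 (q = 3.95e-06, set B -1.79), Gbp4 by -3.32 ± 0.39 (q = 5.28e-06, set B -1.83) and Cd274 by -3.05 ± 0.37 (q = 6.06e-06, set B -1.67). Gbp2b differed by -2.34 ± 0.26 (q = 3.7e-06). Nos2 was close to 0, at 0.0687 ± 0.0997 CPM (-10.30 ± 1.79, q = 0.000154, set B -5.71).

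The MHC class I list was lower in 18 of 19 members, and 19 when adjusted over the list alone (median -1.10, set B -0.62, adjusted exact p = 0.00316). Camera gave 3.61e-21, against an adjusted p = 0.0785 with an estimated correlation. MHC class II was lower in 9 of 11 members, and 10 when adjusted over the list alone (median -0.73, set B -0.70, adjusted exact p = 0.00728). Camera gave 6.57e-05, against an adjusted p = 0.269 with an estimated correlation. Tap1 differed by -1.76 ± 0.19 (q = 2.69e-06, set B -1.05), Tap2 by -1.28 ± 0.16 (q = 6.65e-06, set B -0.70) and H2-DMa by -0.73 ± 0.18 (q = 0.00365, set B -0.64). Fcgr4 differed by -1.75 ± 0.18 (q = 2e-06, set B -1.23), at 138 ± 32.3 CPM. The Fc receptor list was called lower with 2 of 5 members (median -0.21, camera 0.0215), against an adjusted p = 0.179 with an estimated correlation.

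Monocyte-derived genes were lower in 13 of 14 members, and 14 when adjusted over the list alone (median -3.41, set B -2.05, adjusted exact p = 0.00316). Camera gave 1.76e-13, against an adjusted p = 0.0785 with an estimated correlation. F10 differed by -6.87 ± 0.92 (q = 1.4e-05), the matrix gene Fn1 by -3.96 ± 0.57 (q = 2.5e-05) and Itgal by -2.86 ± 0.31 (q = 2.69e-06). The border macrophage list was higher in 17 members when adjusted over the list alone (set B median 0.86, adjusted exact p = 0.00316). Camera gave 3.01e-14, against an adjusted p = 0.104 with an estimated correlation. Cbr2 was higher by 1.99 ± 0.30 (q = 3.97e-05, set B 1.203), Igf1 by 1.72 ± 0.29 (q = 0.000105) and Gas6 by 1.69 ± 0.28 (q = 8.63e-05). Slc40a1 was higher by 3.55 ± 0.56 (q = 6.66e-05, set B 2.60), Ccl24 by 3.01 ± 0.54 (q = 0.00021, set B 1.99) and Siglech by 2.93 ± 0.37 (q = 8.64e-06, set B 2.47). The microglia list was higher in 8 of 9 members, also when adjusted over the list alone (median 1.48, set B 1.05, camera 6.62e-08) and stayed called with an estimated correlation (adjusted p = 0.0427). Fcrls was higher by 2.22 ± 0.35 (q = 6.36e-05, set B 1.32) and Csf1r by 0.54 ± 0.11 (q = 0.000452).

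The prostaglandin synthase Ptgs2 differed by -2.75 ± 0.29 (q = 2.69e-06, set B -2.19), Il1b by -1.92 ± 0.33 (q = 0.000144, set B -1.99), C3 by -3.79 ± 0.50 (q = 1.08e-05) and Ccl5 by -4.20 ± 0.71 (q = 0.00012). Oas2 was higher by 1.01 ± 0.17 (q = 0.000125). Cholesterol synthesis was lower in 5 of 16 members, and 7 when adjusted over the list alone (median -0.58, camera 0.00339, against an adjusted p = 0.357 with an estimated correlation). Mvd of this list differed by -1.36 ± 0.24 (q = 0.000188). Digestion-induced genes were higher in 9 of 18 members and lower in 1 (median 0.63, camera 8.46e-05, against an adjusted p = 0.168 with an estimated correlation).

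Among markers of other cells, fibroblast genes were higher in 9 of 10 members, and 10 when adjusted over the list alone (median 1.98, set B 1.26, camera 0.000157, against an adjusted p = 0.303 with an estimated correlation). Col1a1 was higher by 1.77 ± 0.47 (q = 0.00632, set B 1.26 with q = 0.0749). Neutrophil genes were lower in 10 of 11 members and higher in 1 (median -7.86, camera 0.000159, against an adjusted p = 0.269 with an estimated correlation). The alarmin S100a9 differed by -8.03 ± 1.53 (q = 0.000368, set B -5.77). Elane, the neutrophil elastase (chromosome 10, 79886247 to 79888215, + strand), had 0 counts in all 7 libraries. It was at least 395-fold lower than the 12.9 ± 13.9 CPM with total T cells (0.54 to 32.1). No library of this group is in set A, where the neutrophil score with total T cells was 3.09 to 5.43, against 2.10 and 3.25 in set B, so these values hold part of the difference between the sets. The list stayed called in set B (median -5.09, 4 of 8 members lower, camera 0.00153), and Elane with the set as a term (q = 0.0400). Mast-cell genes were called lower with 2 of 9 members (median -0.81, camera 0.0404, against an adjusted p = 0.507 with an estimated correlation). The copy gene Rps27 follows the library sets (-8.01 ± 1.28, q = 6.94e-05, set B -0.89 with q = 0.587). By the exact tests 17 of 25 lists passed, and the mast-cell list did not. Beyond the lists above these were alternative activation (score difference -0.940), IL-17 and NF-kB targets (-0.490), costimulation (-0.713), cytokine receptors (-0.107), dendritic cells (-1.37) and B cells (0.655).

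Against no T cells, few genes were called for the IL-6Ra/IL-21R group, and most of these were lower. The IFN-gamma response list was not called over all libraries (median -0.06, no member called, camera 0.888, unadjusted exact p = 0.979 over 1716 splits). This does not show that the groups are alike. In set B its median was 0.34 and camera called it higher (0.000992, against an adjusted p = 0.650 with an estimated correlation), while its score there, 0.333 higher, did not pass (unadjusted exact p = 0.214 over 28 splits). The lowest score of the group, 4.11, was that of its set C library. Of the 147 called genes 16 were higher and 131 lower (1368 unadjusted), and 37 were among the 41 genes more than 8-fold lower in set B than in set A. The count depends much on the fit. Leaving out 1 library gave from 72 to 302, females alone 14, limma 47, DESeq2 256, no filter on low counts 564, and a fit with the library set as a term 9. Set B alone gave 69, of which 7 were among the 147. Higher were Dpy19l4 (0.66 ± 0.10, q = 0.00308, set B 0.74), the sphingosine phosphate receptor S1pr2 (0.54 ± 0.12, q = 0.021, set B 0.85) and Arrdc3 (0.57 ± 0.11, q = 0.00615). Lower were S100a9 (-8.82 ± 1.42, q = 0.00308, set B -3.89 with q = 0.324) and the antimicrobial gene Camp (-9.47 ± 1.44, q = 0.00308). Elane, with 0 counts in this group, had 0 to 298 CPM without T cells (64.4 ± 117), with 0 counts in 2 of 6 libraries. Neutrophil genes were lower in 8 of 11 members (median -8.31, camera 5.45e-09, against an adjusted p = 0.260 with an estimated correlation). No library of this group is in set A, so these neutrophil values also hold the difference between the sets. Without T cells the neutrophil score was 3.71 to 7.21 in the 4 libraries of set A and -0.57 and 1.13 in the 2 of set B, against -0.67 to 0.56 with these T cells. In set B alone the list was not called (median -1.66, camera 0.595), nor was any member. The set as a term left the list called (-4.58, camera 0.00525) but not Elane (q = 0.212), Camp (q = 0.137) or S100a9 (q = 0.212). Camera also called 7 lists without a called member, none of which held with an estimated correlation (adjusted p = 0.546 to 0.693). Lower were the monocyte-derived (median -0.63, 4.68e-05), cell-cycle (-0.34, 0.000922), type I interferon (-0.21, 0.00398), endothelial (-0.91, 0.00452) and mast-cell lists (-0.78, 0.0099). Higher were the border macrophage (0.28, 0.0343) and fibroblast lists (0.65, 0.0416). With the library set as a term the border macrophage (-0.40), fibroblast (-0.17) and type I interferon medians (0.0581) changed sign. The fibroblast median was also negative in set B (-0.32) and in females (-0.0617), and the type I interferon median positive there (0.10 and 0.0413). No list passed by its score.

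Macrophages with IL-22-deficient T cells had few genes called against those with total T cells, and the number depended much on the fit. The glycoprotein gene Olfml3 (chromosome 3, 103722222 to 103738001, - strand) was higher by 1.34 ± 0.18 (q = 0.000971), at 161 ± 28.8 against 63.1 ± 8.44 CPM. Its set B value was 1.23 with q = 0.372. Of the 11 called genes 8 were higher and 3 lower (2194 unadjusted). In set B alone edgeR called 0 (842 unadjusted), DESeq2 called 724 in all libraries, no filter on low counts gave 1219, and leaving out 1 library gave from 1 to 775. Among 56 splits 6 reached 11 calls. Also higher were Tmem119 (1.14 ± 0.21, q = 0.0408), Serpinf1, which inhibits vessel growth (1.09, q = 0.0408), and Pmepa1, which damps TGF-beta signals (1.11, q = 0.0408). The others were Rab6b (1.29, q = 0.0408), Fam213a (1.35, q = 0.0473), Bank1 (1.54, q = 0.0404) and Intu (1.64, q = 0.0408). Lower were Clec4e, a sensor of mycobacterial lipids (-2.61 ± 0.52, q = 0.0473), Cers6 (-1.99, q = 0.0473) and Tle3 (-1.03, q = 0.0473). Gbp2 (-1.70 ± 0.47, q = 0.0649, set B -0.41) and Fcrls (1.55 ± 0.37, q = 0.0573) did not pass.

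The microglia list was called higher with 2 of 9 members, and 8 when adjusted over the list alone (median 1.14, camera 4.32e-12). It stayed called with an estimated correlation (adjusted p = 0.00496). The other camera calls against total T cells had no called member and were lost with an estimated correlation (adjusted p = 0.250 to 0.544). Higher were the border macrophage (median 0.92, 8.19e-13), fibroblast (1.02, 0.000119), B-cell (0.66, 0.0187) and digestion lists (0.20, 0.0362). Lower were the monocyte-derived (-1.83, 4.87e-08), IFN-gamma response (-0.66, 7.02e-08), MHC class I (-0.46, 7.02e-08), neutrophil (-4.41, 0.00291) and mast-cell lists (-0.80, 0.0362). When adjusted over the list alone, 14 of 17 border macrophage genes were higher, and 11 of 14 monocyte-derived, 8 of 24 IFN-gamma and 9 of 19 MHC class I genes were lower. No score passed (56 splits, lowest adjusted exact p = 0.223). All IL-22 libraries are in set B, and 3 of the 5 with total T cells are in set A, so these values hold part of the difference between the sets. In set B alone camera did not call the IFN-gamma response (median -0.11, 0.743), MHC class I (-0.0593, 0.229), neutrophil (-1.87, 0.102), B-cell (0.29, 0.115) or digestion lists (-0.0125, 0.360). It still called the microglia (0.63, 3.93e-08), border macrophage (0.26, 7.67e-05), monocyte-derived (-0.91, 2.6e-06), fibroblast (0.97, 4.5e-09) and mast-cell lists (-1.14, 0.0315). Of these only the microglia list held with an estimated correlation (adjusted p = 0.0291).

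Against no T cells, macrophages with IL-22-deficient T cells had higher Fcgr4, and their other differences depended on the test. Fcgr4 was the 1 gene called (1.32 ± 0.20, q = 0.0115, 1187 unadjusted), at 331 ± 83.0 against 134 ± 19.0 CPM, with a set B value of 1.40 (q = 0.069). A fit with the library set as a term called 71 genes, 64 of them higher, with Fcgr4 at q = 0.00185. Without the filter on low counts 499 were called, and DESeq2 called 152. Without library no T cells F1 edgeR called 0 genes, and in females alone it called none either. The Fc receptor list was higher in 5 of 5 members when adjusted over the list alone (median 0.40, camera 4.24e-09) and stayed called with an estimated correlation (adjusted p = 0.00246). By the exact tests 6 lists passed, each at an adjusted p = 0.0496 over 84 splits. These were MHC class II (score difference 0.691), MHC class I (0.534), complement (0.447), Fc receptors (0.563), chemokines (0.597) and costimulation (0.540). These splits ignore the library sets. With splits within sets none passed, as 10 splits allow no exact p under 0.1. The IFN-gamma score differed by 0.989 (adjusted exact p = 0.085). Camera called 17 lists, 16 of them lost with an estimated correlation (adjusted p = 0.0882 to 0.586). Highest were the IFN-gamma response (median 0.86, 1.71e-17, 13 of 24 when adjusted over the list alone), MHC class I (0.53, 1.98e-17, 15 of 19) and MHC class II (0.69, 3.18e-08, 6 of 11). Cholesterol synthesis (0.44), chemokines (0.26), complement (0.23), costimulation (0.22), cytokine receptors (0.16), monocyte-derived genes (0.31) and IL-17 and NF-kB targets (0.10) were also called higher. Border macrophage (-0.42), cell-cycle (-0.44), neutrophil (-5.19), digestion (-0.11), endothelial (-0.87) and type I interferon genes (-0.13) were called lower. All IL-22 libraries are in set B, and some of these directions turned within it or with the set as a term. The IL-17 and NF-kB median became -0.29 in set B (called lower by camera, 0.0105) and -0.24 with the set as a term. Camera's direction for neutrophil and type I interferon genes turned to higher in both fits, not called, at medians of -0.27 and -0.0177 in set B and -1.43 and 0.0767 with the term. The chemokine median fell to -0.0244 in set B and -0.0697 with the term, while camera's direction stayed. The class I gene H2-K1 (0.72 ± 0.16, q = 0.111) and the monocyte attractant Ccl8 (1.77 ± 0.36, q = 0.0689) did not pass.

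With T cells that lacked T-bet, IFN-gamma or IL-17A/F, macrophages had lower IFN-gamma response, MHC and monocyte-derived genes and higher border macrophage and fibroblast genes than with total T cells. Called genes numbered 3797 for T-bet (1884 higher, 1913 lower), 4665 for IFN-gamma (2199 and 2466) and 3178 for IL-17A/F (1594 and 1584). Leaving out 1 of a group's 2 libraries gave as few as 1482, 2052 and 1002, and with the library set as a term 6, 48 and 3 were called. For these groups that term rests on library IL-6Ra/IL-21R M4 alone, the 1 library of its group in set C. It stood apart from the rest of its group, which is all in set B. The term therefore cannot tell the set from what is particular to that library. With it the directions turned for IL-17A/F for the IFN-gamma response (median 0.53), MHC class II (1.13) and MHC class I (0.0397), and camera's direction turned for fibroblast genes (median 0.0680). For T-bet they turned for MHC class II (0.57) and, by camera's direction, for the IFN-gamma response (median -0.0871). No list score passed (21 splits, lowest adjusted exact p = 0.132, 0.108 and 0.149). The smallest exact p that 21 splits allow is 0.0476, so after adjustment over 25 lists hardly any outcome could pass. No camera call held with an estimated correlation (adjusted p = 0.186 to 0.683).

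The IFN-gamma response list was lower in 15 of 24 members for T-bet (median -1.23), 18 for IFN-gamma (-1.84) and 8 for IL-17A/F (-0.83). Adjusted over the list alone these were 18, 20 and 9, and camera gave 1.41e-05, 1.47e-07 and 0.00899. Gbp2 differed by -2.59 ± 0.58 for T-bet (q = 0.00209) and -1.68 ± 0.55 for IL-17A/F (q = 0.0275), and Gbp4 by -4.62 ± 0.74 for IFN-gamma (q = 7.66e-05). Cxcl9 differed by -4.37 ± 1.12 for T-bet (q = 0.0054) and by -6.34 ± 1.26 for IFN-gamma (q = 0.000558). Nos2 differed by -8.16 ± 2.77 for T-bet (q = 0.0286) and -6.97 ± 2.54 for IL-17A/F (q = 0.0461). MHC class I was lower in 16, 19 and 9 of 19 members (medians -1.05, -1.41 and -0.71, camera 1.06e-09, 2.41e-13 and 9.22e-05), with the same counts when adjusted over the list alone. MHC class II was lower in 7, 8 and 2 of 11 (-0.89, -1.43 and -0.44, camera 0.000384, 6.47e-06 and 0.0327), and in 9, 11 and 2 when adjusted over the list alone. Tap1 differed by -1.83 ± 0.30 (q = 0.000176), -2.41 ± 0.31 (q = 1.21e-05) and -1.20 (q = 0.00503). H2-DMa differed by -1.08 ± 0.27 for T-bet (q = 0.0043), and the class II chain H2-Ab1 by -1.46 ± 0.31 for IFN-gamma (q = 0.00112), at 5459 ± 611 against 14796 ± 2169 CPM. H2-DMb2 differed by -1.97 ± 0.51 for IL-17A/F (q = 0.00751). With the library set as a term, H2-DMa (0.44), H2-Ab1 (0.11), H2-DMb2 (0.38) and Nos2 for IL-17A/F (0.73) changed sign. Fc receptors were lower in 3 of 5 members for T-bet (-0.35, camera 0.0263) and 3 for IFN-gamma (-0.61, 0.00241). Fcgr4 differed by -2.53 ± 0.29 for IFN-gamma (q = 3.64e-06) and stayed called with the set as a term (-1.88, q = 0.0241). That term rests on library IL-6Ra/IL-21R M4 alone for this group.

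Monocyte-derived genes were lower in 13, 12 and 12 of 14 members, and in 14, 14 and 13 when adjusted over the list alone (medians -3.57, -3.15 and -3.03, camera 4.55e-10, 4.33e-08 and 1.11e-07). Ccr2, the receptor that brings monocytes out of the marrow, differed by -2.17 ± 0.33 (q = 8.87e-05), -2.62 ± 0.34 (q = 1.28e-05) and -2.18 ± 0.33 (q = 0.000189). Border macrophage genes were higher in 15, 15 and 11 of 17 members, and in 16, 15 and 11 when adjusted over the list alone (1.67, 1.66 and 1.18, camera 4.55e-10, 1.1e-08 and 1.11e-07). Mrc1 differed by 1.84 ± 0.34 for T-bet (q = 0.000446), 1.80 ± 0.34 for IFN-gamma (q = 0.000378) and 1.62 ± 0.34 for IL-17A/F (q = 0.00192), and the haemoglobin receptor Cd163 by 2.85 ± 0.46 for IFN-gamma (q = 8.4e-05). Microglia genes were higher in 6, 5 and 4 of 9, and in 7, 5 and 6 when adjusted over the list alone (1.12, 1.07 and 1.17, camera 7.53e-05, 0.000188 and 0.000264). The IL-17 and NF-kB targets were not called as a list. Of these, the NF-kB inhibitor Nfkbia differed by -0.77 ± 0.16 for T-bet (q = 0.000849), -0.90 ± 0.16 for IFN-gamma (q = 0.000167) and -1.05 ± 0.16 for IL-17A/F (q = 0.000178). Tnf differed by -0.91 ± 0.25 for IFN-gamma (q = 0.00726) and -1.05 ± 0.26 for IL-17A/F (q = 0.00522), and was not called for T-bet (-0.44, q = 0.184). Steap4 differed by 3.19 ± 0.63 for T-bet (q = 0.000715), 3.26 ± 0.63 for IFN-gamma (q = 0.000422) and 2.08 ± 0.63 for IL-17A/F (q = 0.0185). For IL-17A/F it changed sign with the set as a term (-0.23). Digestion genes were higher for T-bet (0.47, camera 0.0263) and IL-17A/F (0.38, 0.0327), and cholesterol genes lower for IFN-gamma (-0.79, 0.0173) and IL-17A/F (-0.66, 0.0156). Cell-cycle genes were lower for T-bet (-0.82, camera 0.00604, 8 of 25).

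Markers of other cells moved with these groups as well. Fibroblast genes were higher in 9, 9 and 10 of 10 members, and in 10 each when adjusted over the list alone (medians 3.45, 3.49 and 3.16, camera 1.06e-09, 9.76e-09 and 4.13e-09), and dendritic cell genes were lower in 5, 7 and 3 of 10 (-2.88, -2.78 and -1.79, camera 0.0263, 0.0114 and 0.0256). The collagen gene Col12a1 (chromosome 9, 79598991 to 79718831, - strand) differed by 4.72 ± 0.78 (q = 0.000195), 4.79 ± 0.78 (q = 9.52e-05) and 4.40 ± 0.78 (q = 0.000547). Slc26a7, an anion transporter, differed by 4.93 ± 0.57 (q = 6.89e-06), 5.06 ± 0.57 (q = 2.9e-06) and 4.51 ± 0.56 (q = 4.93e-05). Rps29 (chromosome 12, 69157722 to 69159186, - strand), which follows the library sets, differed by -12.04 ± 3.28 for T-bet (q = 0.00775).

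Against no T cells, camera called the fibroblast list higher and the cell-cycle list lower in these 3 groups. With the library set as a term the fibroblast medians turned to -0.73 for T-bet, -0.76 for IFN-gamma and -1.15 for IL-17A/F. For these groups the term rests on library IL-6Ra/IL-21R M4 alone. Called genes numbered 913 for T-bet (530 higher, 383 lower), 1727 for IFN-gamma (861 and 866) and 756 for IL-17A/F (467 and 289), and 0, 0 and 33 with the library set as a term (edgeR, 723 unadjusted for T-bet and 762 for IFN-gamma). Leaving out 1 of a group's 2 libraries gave as few as 0 for T-bet, 1 for IFN-gamma and 3 for IL-17A/F. No list score passed (28 splits, lowest adjusted exact p = 0.149, 0.0992 and 0.149), and no camera call held with an estimated correlation (adjusted p = 0.337 to 0.899). The smallest exact p that 28 splits allow is 0.0357, which after adjustment over 25 lists leaves little room to pass. The IFN-gamma response list was called higher for IL-17A/F with 10 of 24 members, and 13 when adjusted over the list alone (median 0.74, camera 1.95e-07). It was not called for T-bet (0.21, 0.0783) or IFN-gamma (-0.18, 0.727), which does not show that the groups differ. For IL-17A/F the GTPases Gbp2b (1.69 ± 0.35, q = 0.00886) and Gbp8 (2.14 ± 0.37, q = 0.00512), the class II regulator Ciita (1.10 ± 0.33, q = 0.0466) and Fcgr4 (1.24 ± 0.23, q = 0.00531) rose. Gbp8 (3.61, q = 0.0187) and Fcgr4 (1.88, q = 0.0372) stayed called with the set as a term. MHC class I was called higher for IL-17A/F (0.32, camera 0.00122) and lower for IFN-gamma (-0.49, 0.00293). MHC class II was called lower for IFN-gamma (-0.80, 0.000858), with H2-DMb2 at -2.92 ± 0.58 (q = 0.00413), and not for IL-17A/F (0.17, 0.711). With the set as a term the MHC class I (0.37) and class II medians (0.78) for IFN-gamma turned positive.

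Fibroblast genes were higher than without T cells in 8 of 10 members for T-bet (median 2.30, camera 3.17e-09), 9 for IFN-gamma (2.25, 2.79e-08) and 4 for IL-17A/F (1.77, 4.72e-07). Adjusted over the list alone these were 9 each. The matrix gene Svep1 differed by 5.28 ± 0.90 for T-bet (q = 0.00379) and 4.77 ± 0.90 for IFN-gamma (q = 0.00323). Cell-cycle genes were called lower in 7 of 25 members for T-bet, 7 for IFN-gamma and 0 for IL-17A/F, and in 17, 11 and 2 when adjusted over the list alone (-1.35, -0.92 and -0.78, camera 6.37e-10, 5.58e-05 and 0.00258), with the cyclin Ccna2 at -2.98 ± 0.47 for T-bet (q = 0.00323). Monocyte-derived genes were lower in 3 of 14 for T-bet (-1.54, camera 8.78e-06) and 4 for IFN-gamma (-1.66, 0.000858), with Ccr2 at -1.61 ± 0.32 for IFN-gamma (q = 0.00417). With the set as a term the log2 fold change of Ccr2 changed sign to 0.0813. Type I interferon genes were called lower for T-bet (-0.40, 0.0175) and IFN-gamma (-0.38, 0.0427). IL-17 and NF-kB targets were called higher for T-bet (0.38, 0.00453), where Tnfaip3, a brake on NF-kB, rose by 0.98 ± 0.17 (q = 0.00379). Further calls were lower osteoclast genes for T-bet (-1.73, 0.00714), lower dendritic cell genes for IFN-gamma (-1.96, 0.0112) and higher complement genes for IL-17A/F (0.12, 0.0379), where camera's direction turned with the set as a term (median 0.0573). Cxcl13, which draws B cells, rose by 3.52 ± 0.80 for IFN-gamma (q = 0.00801) and 4.25 ± 0.79 for IL-17A/F (q = 0.00531). Retnla, a marker of alternative activation, changed by -4.30 ± 1.12 for IL-17A/F (q = 0.0279).

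The mean of the 6 T-cell groups differed from no T cells in 664 genes, 246 higher and 418 lower (2656 unadjusted). Females alone gave 236, no filter on low counts 1534, and leaving out 1 library from 343 to 956. With the library set as a term 79 were called, and the medians of the fibroblast (-0.76), chemokine (-0.17), complement (-0.10) and type I interferon lists (0.15) changed sign. The IFN-gamma response was higher in 9 of 24 members, and 12 when adjusted over the list alone (median 0.45, camera 2.29e-09), and its median was 1.16 with the set as a term. Fcgr4 rose by 0.64 ± 0.15 (q = 0.0108) and Gbp2b by 1.07 ± 0.23 (q = 0.00666), and both stayed called with the set as a term (1.06 with q = 0.0241 and 1.59 with q = 0.0451). For the groups found in set C alone that term rests on library IL-6Ra/IL-21R M4. Cxcl13 rose by 3.09 ± 0.60 (q = 0.00317), Ccl8 by 1.49 ± 0.28 (q = 0.00243) and Tnfaip3 by 0.67 ± 0.11 (q = 0.000751). The cell-cycle list was lower in 9 of 25 members, and 16 when adjusted over the list alone (median -0.57, camera 1e-10). Ccna2 changed by -1.15 ± 0.21 (q = 0.0021) and Rrm2, which makes DNA building blocks, by -1.03 ± 0.23 (q = 0.00932). Neutrophil genes were lower in 8 of 11 members (-4.48, 0.00165), with Camp at -6.45 ± 0.95 (q = 0.000512). The high neutrophil scores without T cells were those of set A, and with the set as a term neither the list (-1.30, 0.341) nor Camp (-4.34, q = 0.621) was called. Camera also called MHC class I (0.25, 0.000412), IL-17 and NF-kB targets (0.13, 0.00904), complement (0.07, 0.0201), Fc receptors (0.10, 0.0201), chemokines (0.10, 0.0218), cytokine receptors (0.10, 0.0218) and fibroblast genes (1.02, 0.000119) higher. It called type I interferon (-0.22, 0.0138) and osteoclast genes (-0.90, 0.0201) lower. None of these calls held with an estimated correlation (adjusted p = 0.365 to 0.634). Of the 664 genes 37, all lower, were among the 41 genes more than 8-fold lower in set B than in set A, such as Rps29 (-7.49 ± 1.05, q = 0.000512).

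Any difference among the 7 groups was called for 4861 genes (6036 unadjusted) and for 1833 with the library set as a term. Males and females differed in 7 genes, 4 higher in males and 3 lower (918 unadjusted). Without the filter on low counts 290 were called, and in set A alone 0 (edgeR, 461 unadjusted). Xist, which silences an X chromosome in females (chromosome X, 103460366 to 103483254, - strand), differed by -6.49 ± 0.57 (q = 3.83e-07). The Y-linked Ddx3y (7.16 ± 0.71), Eif2s3y (7.28 ± 0.65), Kdm5d (6.42 ± 0.61) and Uty (6.70 ± 0.78) were higher, and the X-linked Kdm6a was lower (-0.52 ± 0.09, q = 0.0244). Ccdc88a was lower as well (-0.47 ± 0.09, q = 0.0441). Camera called the cell cycle (median -0.25, 2.26e-06), IL-17 and NF-kB targets (-0.25, 0.000334) and chemokines (-0.26, 0.0134) lower in males. It called neutrophil (1.87, 0.0134) and mast-cell genes (0.59, 0.0188) higher. Camera's direction turned for neutrophil genes in set A (median 0.52) and for IL-17 and NF-kB targets in set B (-0.0860), neither called there. No member was called, and none of these held with an estimated correlation (adjusted p = 0.675 to 0.743). Sex by group was tested between the no T-cell and IL-6Ra/IL-21R groups alone. No gene was called by edgeR (724 unadjusted of 12769) or by limma, while edgeR called 67 without the filter. The males without T cells are all in set A and the males of the other group in sets B and C. This test therefore also holds the difference between sets.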

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

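The tests of shared sequence and of monocyte-derived genes were written before their results were seen, and the other tests of this part were chosen after. Of 87 tests for a library far from its group (29 measures in the groups of 5, 6 and 7 libraries), 7 passed, where chance alone passes about 1 in 20. Library no T cells F1 had a complement score of 8.23, with the others of its group at 8.56 to 8.66. Library no T cells M1 had a B-cell score of 4.94, with the others at 5.28 to 5.48. Library total T cells F4 had 16989 genes detected, with the others at 14534 to 15066. Library total T cells F1 had a complement score of 8.54, with the others at 8.89 to 9.01. Library IL-6Ra/IL-21R M4 stood apart in 3 measures. Its mitochondrial share was 1.30% against 2.78% to 3.47%, its fibroblast score 7.90 against 4.64 to 5.89 and its endothelial score 3.87 against 1.12 to 2.26. It is the 1 library of its group in set C. Over that set mitochondrial shares ran from 1.00% to 5.05%, fibroblast scores from 6.84 to 7.90 and endothelial scores from 1.55 to 3.87. These gaps therefore cannot be told from the difference between sets. Groups of 2 libraries were too small for this test, but library IFN-gamma F1 had a mitochondrial share of 5.05%, with the other libraries of set C at 1.00% to 1.44%, and the fewest genes detected of all libraries (13225). Without it 2052 genes were called for its group against total T cells instead of 4665, and 1 against no T cells instead of 1727.

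In 20 libraries, sets B and C, some ribosomal protein genes were near 0, while the 7 libraries of set A had them at high levels (Rps29 at 313.5 to 465.2 CPM in set A and 0 to 2.51 in the others). Of 41 genes more than 8-fold lower in set B than in set A, 25 had a near-identical copy elsewhere, against 438 of 7566 other genes. The 41 include the Y-linked Ddx3y and Eif2s3y and the neutrophil genes Mpo, Ngp, Ltf and Ctsg. Set A holds male libraries, while the set B libraries without T cells or with total T cells are all female. Among the 41 the share with a copy was 10.5 times as high (Fisher's exact test, two-sided p = 9.03e-21). Reads shared with copies and counted in another way would give this. But 26 of the 41 were ribosomal protein genes, against 46 of 7643 others, and such genes often have a copy (47 with, 25 without). The ratio therefore cannot tell shared reads from lower levels of ribosomal protein transcripts. Ribosomal protein genes with such a copy had a median log2 ratio of set A to set B of 1.88 (quartiles 0.94 and 5.50). Those without one were also lower in set B (1.32, quartiles 0.31 and 2.20), which lower levels of these transcripts would give. Some of them share shorter stretches with another gene (43.9% of Rps29), so shared reads are not excluded there, and both explanations stay open.

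In the 7 libraries of set C, which have the lowest ribosomal protein counts, 10 of 10 fibroblast markers were higher (median log2 ratio 2.58), as RNA of fibroblasts among the sorted cells would give. A lower share of macrophages would raise every other cell type alike. Endothelial markers had a median log2 ratio of 0.25, with 7 of 12 higher, which argues against it. Mast-cell markers go the other way, with 9 of 9 higher (median 0.93), so it is not excluded. B-cell markers were higher in 2 of 4 (0.21). Of the dendritic cell, osteoclast and erythroid markers 1 of 10, 1 of 6 and 1 of 6 were higher (-1.28, -0.91 and -0.75). Border macrophage genes were higher in 15 of 17 (0.65) and microglia genes in 5 of 9 (0.10). These values also hold differences between groups, as set C has no library with total T cells or without T cells. Neutrophil markers had a median of -1.57, but the libraries they were compared with include set A, where neutrophil scores ran high. The genotype of the T cells cannot be told apart from the set for 6 of these libraries, as their groups are in set C alone. The seventh, IL-6Ra/IL-21R M4, had a fibroblast score 2.01 above the highest of the other 6 libraries of its group, whose range was 1.24. The rule, written after the data were seen, counted a gap above that range as evidence against the genotype. Fibroblast scores were 6.84 to 7.90 in set C and 3.72 to 6.13 in the other libraries. Still, 1 library cannot decide between set and genotype, so no verdict is drawn.

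IFN-gamma response genes were higher with total T cells, and a difference between library sets is excluded as the whole cause, since the exact permutation test of the list score with splits within sets gave p = 0.00476, the smallest that 210 splits allow. A larger share of monocyte-derived cells among the sorted cells stays open. With the monocyte list score as a covariate, the median log2 fold change of the IFN-gamma list was 0.88 instead of 1.49. Camera still called the list (adjusted p = 5.47e-15), while none of its 24 members was called (edgeR; 19 before), as the median SE grew from 0.27 to 0.38 and the fold shrank, with 3 genes called in all (1277 unadjusted). The rule written before counted a median above 0.5 of its value, with the list still called, as evidence against this explanation. It was met, with 59.1% kept. The spread of the list median itself was not estimated, as the SE given is that of single genes. The rule was made stricter after the value was seen, so no verdict is drawn from it.

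Random splits that ignore the library sets exclude chance for the gene counts of 6 comparisons, but not a difference between sets. They are given here as the real count and the highest of the other splits, with the number of splits as large, the real one included. For total T cells against no T cells these were 2663 and 1609 (1 of 100 splits), for the IL-6Ra/IL-21R group against total T cells 3565 and 2066 (1 of 100), and for the mean of the T-cell groups 664 and 193 (1 of 100). Any difference among the groups gave 4861 and 172 (1 of 100), and males against females 7 and 28 (2 of 100). The IL-6Ra/IL-21R group against no T cells gave 147 and 140 (1 of 100), where the other split placed 4 set A libraries together, and set B alone gave 69 and the set as a term 9. The IL-22 group against no T cells gave 1 and 16 (4 of 84), where the other split held 3 set A libraries. All IL-22 libraries are in set B, and the 10 splits that keep them there are too few for a share under 0.05. For the IL-22 group against total T cells the counts were 11 and 1711 (6 of 56), so chance is not excluded. The split with 1711 follows set A and points to a structure of the samples, and set B alone gave 0 (edgeR, 842 unadjusted).

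Numbers of gene lists called by camera were matched by random splits in most comparisons, so the exact tests of the scores were added. The real and the highest other number were 11 and 15 for total T cells against no T cells (32 of 100 splits), 12 and 15 for the IL-6Ra/IL-21R group against total T cells (20 of 100) and 10 and 16 for the IL-22 group against total T cells (20 of 56). They were 8 and 13 for the IL-6Ra/IL-21R group against no T cells (38 of 100), 12 and 15 for the mean of the T-cell groups (7 of 100) and 5 and 14 for males against females (83 of 100). For the IL-22 group against no T cells they were 17 and 18 (2 of 84). The split with 18 is among the 10 that keep the sets, which are too few for a share under 0.05.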

How the results depend on the processing

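The median-ratio, DESeq2, pseudocount 1 and library set alternatives were chosen after the data were seen, and the others were planned. No paired analysis was possible because the columns carry no replicate numbers, so a block by replicate was not run. A fit on reads recovered from normalized values was not needed, as the table holds raw counts, and TMM scaling was already in use. Where no cause is given below, the cause was not tested. Depth limits the genes with few counts, and a mean of at least 10 was asked for. In the fits by set the calls rest on fewer libraries, and for the groups of 2 the set term rests on library IL-6Ra/IL-21R M4 alone.

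With the library set as a term, of the 149 named results for genes 78 kept their call, 64 fell under the threshold, 1 rose over it and 6 reversed. Of the 124 list results 70 kept their call, 32 lost it and 22 reversed. The numbers of genes called became 79 for the mean of the T-cell groups, 6, 48 and 3 for T-bet, IFN-gamma and IL-17A/F against total T cells, and 0, 0 and 33 against no T cells (edgeR, 723 and 762 unadjusted for T-bet and IFN-gamma). They became 1810 and 2 for the IL-6Ra/IL-21R and IL-22 groups against total T cells, 9 and 71 against no T cells, and 1833 for any difference. Reversed were Ccr2 (IFN-gamma against no T cells, 0.0813), H2-Ab1 (IFN-gamma against total T cells, 0.11) and H2-DMa (T-bet against total T cells, 0.44). For IL-17A/F against total T cells H2-DMb2 (0.38), Nos2 (0.73) and Steap4 (-0.23) reversed.

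List directions, as camera gives them, reversed with the set as a term at these medians, some of which kept their sign. Against total T cells these were MHC class II (1.13), the IFN-gamma response (0.53), MHC class I (0.0397) and fibroblast genes (0.0680) for IL-17A/F, and MHC class II (0.57) and the IFN-gamma response (-0.0871) for T-bet. Against no T cells they were fibroblast genes for T-bet (-0.73), IFN-gamma (-0.76), IL-17A/F (-1.15), IL-6Ra/IL-21R (-0.17) and the mean of the groups (-0.76). Further ones were MHC class II (0.78) and class I (0.37) for IFN-gamma, complement for IL-17A/F (0.0573) and the mean (-0.10), and chemokines (-0.17) and type I interferon (0.15) for the mean. For IL-6Ra/IL-21R border macrophage (-0.40) and type I interferon genes (0.0581) reversed, and for IL-22 neutrophil (-1.43), IL-17 and NF-kB target (-0.24) and type I interferon genes (0.0767). In set B alone the IL-6Ra/IL-21R group reversed against no T cells for fibroblast (-0.32) and type I interferon genes (0.10), and the IL-22 group for neutrophil (-0.27), IL-17 and NF-kB target (-0.29) and type I interferon genes (-0.0177). In set B Isg15 reversed for total T cells (-0.12), and IL-17 and NF-kB targets did between the sexes (-0.0860). In set A neutrophil genes did between the sexes (0.52). In females the IL-6Ra/IL-21R group against no T cells reversed for fibroblast (-0.0617) and type I interferon genes (0.0413).

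Set B alone called 92 genes for total T cells, 827 and 69 for the IL-6Ra/IL-21R group against total and no T cells, and 0 (edgeR, 842 unadjusted) and 2 for the IL-22 group. Set A alone called 0 between the sexes (edgeR, 461 unadjusted). Females alone gave 1564 for total T cells, 236 for the mean of the groups, 1990 and 14 for the IL-6Ra/IL-21R group, and 0 and 0 for the IL-22 group (edgeR, 2018 and 582 unadjusted). Without the filter, so with more genes tested, 1534 were called for the mean, 1219 and 499 for the IL-22 group, 1510 and 1388 for T-bet and IL-17A/F against no T cells, 564 for IL-6Ra/IL-21R against no T cells, 290 between the sexes and 67 for sex by group. Without the sex term the IL-22 group had 4 and 9. With only the compared groups in the fit, T-bet, IFN-gamma, IL-17A/F and IL-22 against total T cells had 1912, 1934, 1180 and 0 (edgeR, 2099 unadjusted for IL-22), and IFN-gamma and IL-22 against no T cells had 1099 and 42.

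DESeq2 called 724 and 152 for the IL-22 group, 256 for IL-6Ra/IL-21R and 1154 for IL-17A/F against no T cells, and 11 between the sexes. Limma called 105 (pseudocount 5) and 74 (pseudocount 1) for IL-22 against total T cells, and 47 and 36 for IL-6Ra/IL-21R against no T cells. Median-ratio factors gave 4 for IL-22 against total T cells, and the other counts stayed within 1.5 times. No named gene reversed under no filter, no sex term, females alone, limma, DESeq2, median-ratio factors or only the compared groups. Of the 124 camera calls, 3 held with an estimated correlation and 68 with fry.

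Leaving out each library in turn gave 1717 (without total T cells M1) to 2981 for total T cells, 343 (without no T cells M1) to 956 for the mean of the groups, and 2431 to 3841 for IL-6Ra/IL-21R against total T cells. Against total T cells, T-bet had 1482 (without T-bet F1) to 3979, IFN-gamma 2052 (without IFN-gamma F1) to 4776, IL-17A/F 1002 (without IL-17A/F F1) to 3405 and IL-22 1 (without total T cells F1) to 775 (without total T cells F3). Against no T cells, T-bet had 0 (without T-bet F1) to 839, IFN-gamma 1 (without IFN-gamma F1) to 2105, IL-17A/F 3 (without IL-17A/F F2) to 723, IL-6Ra/IL-21R 72 (without no T cells M1) to 302 (without IL-6Ra/IL-21R M4) and IL-22 0 (without no T cells F1) to 11 (without IL-22 F2). Other libraries whose loss moved a count by over 1.5 times were T-bet F2 (2008 against total and 25 against no T cells), IL-17A/F F2 against total T cells (1301), IL-17A/F F1 against no T cells (24), and no T cells F2 for T-bet (588), IL-17A/F (501) and IL-6Ra/IL-21R (95). For the IL-22 group 7 of 8 such fits against total T cells and 8 of 9 against no T cells moved the count by over 1.5 times. The counts for any difference (4134 to 5347), the sexes (5 to 8), sex by group (0 to 0) and called lists (113 to 134) moved less. Where a group was left with 1 library, it was assumed to vary like the other groups. No named gene or list reversed.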

Other observations

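All tests of this part were chosen after the data were seen. Within set C, macrophages with IL-17A/F-deficient T cells were compared with those given T-bet- or IFN-gamma-deficient T cells, 2 libraries against 4, since these 6 libraries share a set. Fcgr4 was the 1 gene called (1.54 ± 0.25, q = 0.0232, 489 unadjusted). The log2 fold changes of 5 of 5 Fc receptor genes were above 0 (median 0.27), with Fcgr4 alone called, and camera called the list with an estimated correlation too (adjusted p = 0.0136). Those of 19 of 19 MHC class I genes (median 0.64) and 11 of 11 MHC class II genes (0.70) were above 0 with none called, with exact permutation p = 0.133 for both scores. Monocyte-derived genes had a median of 0.93 and border macrophage genes one of -0.36, with exact p = 0.0667 for each, the smallest that 15 splits allow.

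A hypothesis from these values is that T cells without IL-17A and F leave the IFN-gamma response of dural macrophages higher than T cells without T-bet or IFN-gamma. The median log2 fold change of the IFN-gamma list was 0.58, with 20 of 24 members above 0 and scores of 5.45 to 5.96 against 4.61 to 5.28. Camera called it (adjusted p = 4.78e-14), but not with an estimated correlation (adjusted p = 0.202), and the exact permutation p was 0.0667, the smallest possible. No member was called (edgeR). The test is too small to decide.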
